A study of Elaeis guineensis with 10 samples.

How the data were processed

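RNA was sequenced from leaf tissue labelled frond 0 of 10 oil palms (Elaeis guineensis), all clones of a single mother palm (ortet). The fruit phenotype label places 5 palms in the mantled group and 5 in the normal group, and the series' design text makes the normal group the reference, so every difference is given as mantled minus normal. Mantled fruit is a floral abnormality of clonal oil palms in which the male organs of the flower develop like carpels. Each palm is a separate plant and 1 library, and replicates were numbered in accession order within a group. The palms are also named by the number in their title, from 673 to 770. The labels give no replicate number, batch, date or pairing.

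RNA was purified with a plant RNA kit and DNA was digested, and KAPA stranded mRNA libraries were sequenced paired-end on a Hiseq2500 instrument, per the labels' protocols. The deposited values are raw counts, 1 table per palm, and were not normalised by the authors. The submitters' processing notes name FastQC 0.11.3, Trim Galore 0.4.0, TopHat2 2.0.13 and HTSeq 0.6.1p1, without parameters. The genome build and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping antisense models cannot be told apart.

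Each table lists 100342 counting units and 5 classes of reads that HTSeq assigned to no unit. Of the units, 92649 have IDs made of a scaffold, the word cds and a pair of numbers, and 7693 have IDs in the style of the MAKER annotation program. The ID without its last number is called the stem here; the files hold 26087 stems. The tables pair no unit with a gene name, a description or coordinates. None of the unit IDs (0 of 100342) matched a name in the RefSeq gene table of the oil palm assembly EG11, so gene names, positions and functions are not given. The 37 gene lists fixed before the data were examined, among them the B-class floral MADS-box genes, DNA methylation, photosynthesis, defence, hormone pathways and markers of other tissues, rest on gene descriptions and could not be applied. No list result exists, and B-class genes and the share of reads from organelles, planned as a library measure, are not analysed here. The naming rule for this case allows at most 2 IDs in each direction, and the 2 with the smallest p-value each way were taken.

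Between 10236532 and 12544294 reads per palm were assigned to units. These were 40.7% to 43.6% of the reads listed. A further 31.9% to 35.7% fell in no unit, 18.2% to 20.6% were ambiguous between units, and 2.78% to 5.72% had no unique alignment. The 5 unassigned classes were left out of library sizes and tests. HTSeq counts carry no molecular identifiers, so the counts measure reads or read pairs and not independent molecules. The libraries were paired-end, and the counting parameters that would settle which of these was counted are not given. Both are called reads here. No pair of libraries within a group was identical or differed by as little as sampling noise: the chi-square of their counts over its degrees of freedom was at least 15.65.

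Counts were tested with edgeR 4.0.16 in R 4.3.3. Units were kept with filterByExpr defaults, which left 32285 units of 17530 stems on 1581 scaffolds, holding 99.03% of the assigned reads. Libraries were scaled by TMM, and mantled and normal palms were compared with a robust quasi-likelihood F test (glmQLFit and glmQLFTest), two-sided, on all 10 palms with no covariate. P-values were adjusted by Benjamini-Hochberg over the units tested, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use the TMM-scaled library sizes, and log2 CPM a prior count of 2. Library measures and component scores were compared with exact two-sided permutation tests over the 252 assignments of 10 palms to 5 and 5. Because the palms lie in clusters on the first component, no correlation of its scores with library measures is given.

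The test was checked on simulated data: 200 units with a mean count of at least 20 were changed by known folds, 50 units per fold, in negative binomial counts drawn from the real means and dispersions and in real counts thinned in 1 group. The alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, upper-quartile factors, no filter, a filter at a mean count of 10, the DESeq2 test, limma-voom (limma 3.58.1) with sample quality weights, non-robust dispersions, 1 surrogate variable (sva 3.50.0), leaving out each palm, and using only palms 753 to 770. Alternatives chosen after the data were seen were 2 or 3 surrogate variables, leaving out palms 687 and 768 together, counts summed per stem, and MAKER-style units alone. The planned sum per gene through a reference was not run, since the reference used here matched none of the units.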

Results

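Leaf transcriptomes were compared between 5 clonal palms bearing mantled fruit and 5 bearing normal fruit, all derived from 1 ortet. The comparison asks whether the fruit phenotype, which affects floral organs, is accompanied by a difference in leaf gene expression among genetically alike palms. Between 10236532 and 12544294 reads per palm were counted, over 100342 counting units, for which the tables give IDs without coordinates or descriptions. Of these, 80122 had at least 1 read in some palm and 20220 had none. The number of units with at least 10 reads ranged from 30327 to 36200 per palm.

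No unit passed the test for a difference between mantled and normal leaves. Among 32285 units tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and consequently 0 passed that threshold with a change of at least 2-fold. The lowest adjusted p was 1 after rounding, and 0 units passed even at 0.25. At the threshold of 0.05 the DESeq2 and limma-voom tests of the same palms also called 0 units. Their lowest adjusted p was 0.996 in DESeq2 and 0.135 in limma-voom, so the absence of units at 0.25 does not hold for limma-voom. At an unadjusted p under 0.05 there were 389 units in edgeR, 192 higher and 197 lower in mantled palms, which is 1.2% of those tested, where 1614 would be reached with uniform p-values. The count at that level was 937 of 79866 units in DESeq2, which ran without the filter on low counts, and 7525 of 32285 in limma-voom, which weighted the palms by quality. It also rose to 2300 in edgeR without mantled replicate 2 and fell to 136 without mantled replicate 5, with 0 units past the adjusted threshold in both cases.

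The precision of the comparison is described by the fitted variation and the standard errors. The biological coefficient of variation common to all units was 0.491, and the median standard error of a log2 fold change was 0.39, with quartiles of 0.32 and 0.48. The median 95% interval reached 0.84 on the log2 scale to either side of the estimate, a 1.79-fold change. For 13422 units, 41.6% of those tested, the interval excluded a 2-fold change in either direction, and for 29910 units (92.6%) it excluded a 4-fold change. These intervals were not adjusted for the number of units.

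Simulated changes gave the sizes that the test could call in this design. When the real counts of 1 group were thinned for 200 of 32280 units, 0 of 50 units changed 1.5-fold and 0 of 50 changed 2-fold were called, against 14 of 50 (28%) changed 4-fold and 34 of 50 (68%) changed 8-fold. In negative binomial counts without the real structure between palms (31330 units), 0%, 0%, 34% and 84% of the units changed 1.5-, 2-, 4- and 8-fold were called. When 2000 units were thinned 4-fold at once, 76.5% were called.

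**Figure D1:**
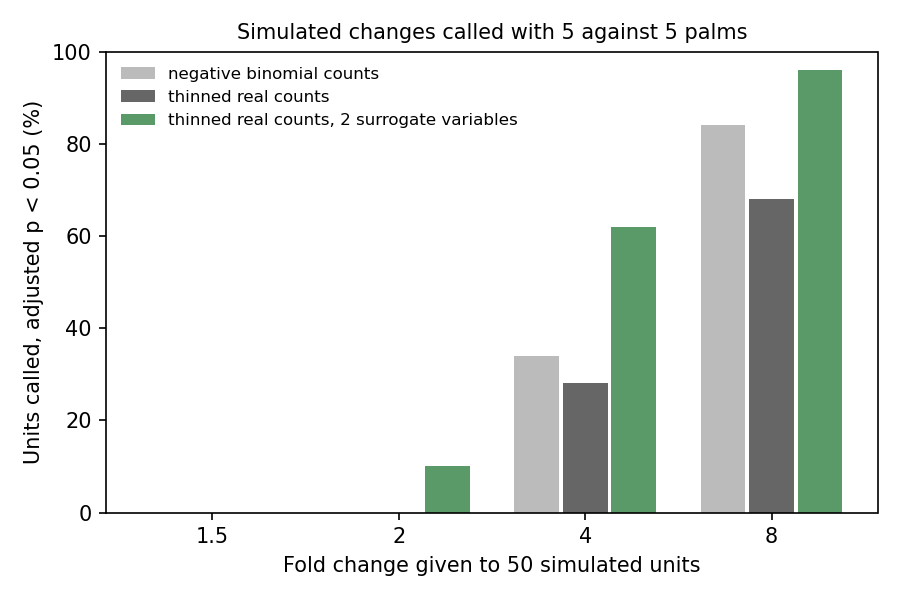
Bars give the percentage of simulated changed units called at an adjusted p under 0.05 (vertical axis) for each fold change given to 50 units each (horizontal axis), for 3 simulations of 5 against 5 palms. At 2-fold the thinned real counts gave 0% and at 8-fold 68%; with 2 surrogate variables as covariates the values were 10% and 96%.

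The units with the smallest p-values are named by their IDs, since the tables hold no gene names, and none passed the adjusted threshold. Unit p5_sc00047_cds_3.6, on scaffold 47, had 1.27 ± 0.18 CPM in mantled palms and 0.463 ± 0.20 CPM in normal palms (SD, n = 5 each), a log2 difference of 1.43 with a standard error of 0.36. Its counts were low, from 14 to 16 reads in mantled and from 3 to 9 in normal palms. Unit p5_sc00178_cds_96.2, on scaffold 178, had 1.02 ± 0.23 against 0.41 ± 0.09 CPM, a log2 difference of 1.29 with a standard error of 0.35, from 11 to 15 and from 3 to 5 reads. Their edgeR p-values were 0.00186 and 0.00278, with an adjusted p of 1 for both.

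In the other direction, unit p5_sc00062_cds_122.2, on scaffold 62, had 10.2 ± 1.9 CPM in mantled and 17.6 ± 1.8 CPM in normal palms, a log2 difference of -0.78 with a standard error of 0.23. Its CPM values did not overlap, from 8.37 to 12.8 in mantled and from 15.5 to 19.8 in normal palms. Unit p5_sc00054_cds_16.5, on scaffold 54, had 3.56 ± 1.6 against 20.6 ± 31.8 CPM, a log2 difference of -2.53 with a standard error of 0.81. That difference rested on normal replicate 5, with 77.4 CPM, where the other normal palms had 3.50 to 8.46 CPM; without it the log2 difference was -0.84. The edgeR p-values of the pair were 0.00545 and 0.00834, with an adjusted p of 1 for both.

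**Figure D2:**
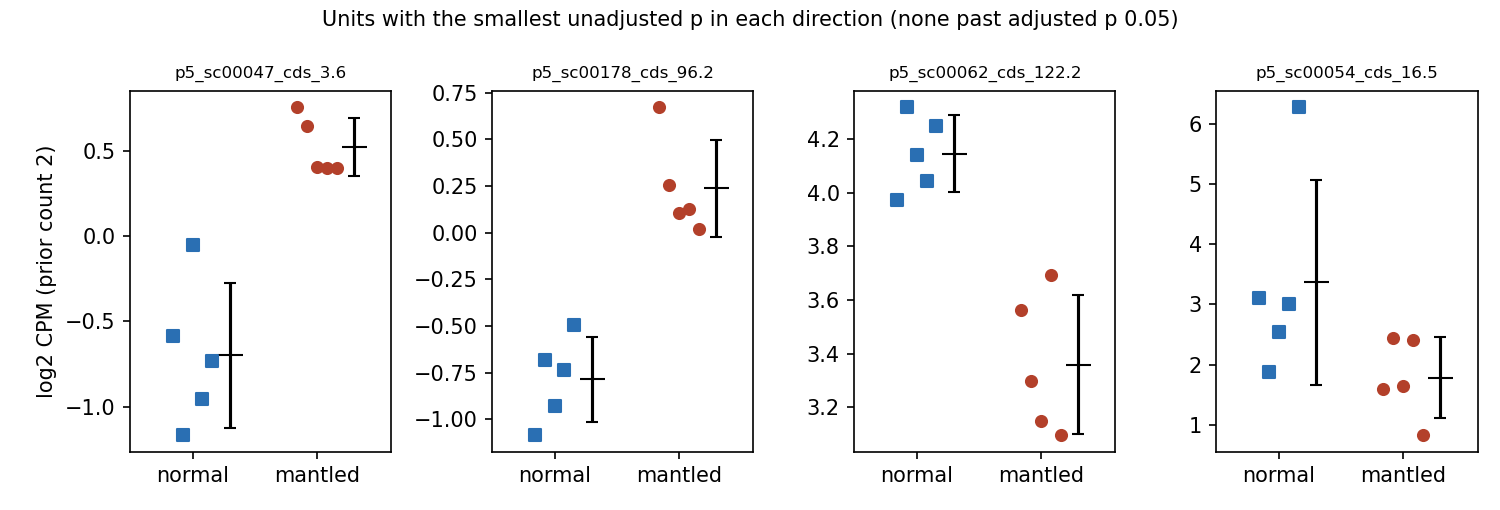
Log2 CPM (vertical axes, prior count 2) of the 4 named units in normal (blue squares) and mantled (red circles) palms, 1 point per palm, with the mean and SD of 5 palms in black; each panel has its own scale. The ranges of the groups are apart in the first 3 panels and overlap for p5_sc00054_cds_16.5, where 1 normal palm lies at 6.28.

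When counts were summed over all units with the same stem, the 2 low-count differences shrank. For stem p5_sc00047_cds_3, with 9 units in the tables, the log2 difference was 0.31 with a standard error of 0.25. For stem p5_sc00178_cds_96, with 4 units, it was 0.17 with a standard error of 0.26. The stem p5_sc00062_cds_122, with 2 units, gave -0.77 with a standard error of 0.21. Its other unit did not pass the filter, and the sum (10.2 and 17.4 CPM) was nearly the named unit alone, so it could hardly differ. The stem p5_sc00054_cds_16, with 5 units, gave -2.48 with a standard error of 0.80. Its named unit rested on normal replicate 5, and the sums were not fitted without that palm. The adjusted p in edgeR was 1 for each of the 4 stems.

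No unit was read in all palms of 1 phenotype and nearly absent from all palms of the other. There were 0 units with at least 20 reads in every mantled palm and at most 1 read in every normal palm, and 0 units with the opposite pattern. The values of the 5 mantled palms lay wholly above or wholly below those of the 5 normal palms in 40 units, 0.124% of those tested, where chance with independent palms gives 0.794%. Of all 126 splits of the palms into 5 and 5, 110 gave at least as many such units as the phenotype. The median of the other splits was 130 units.

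The palms differed widely from each other, and mantled and normal palms were intermingled. The first principal component of log2 CPM held 46.6% of the variance and the second 19.8%. Mantled replicates 1, 3 and 5 (palms 673, 754 and 770) had first-component scores of -90.0, -98.8 and -98.5, while mantled replicate 2 (palm 687) lay at 119.3 and mantled replicate 4 (palm 765) at 54.9. All normal palms lay above mantled replicates 1, 3 and 5, but on both sides of mantled replicates 2 and 4. Normal replicates 1 and 4 (palms 753 and 767) lay at -43.9 and -59.9, and replicates 2 and 3 (palms 758 and 764) at 26.8 and 47.2. Normal replicate 5 (palm 768) lay at 142.9. The group means of -22.6 ± 102.8 and 22.6 ± 81.1 (SD, n = 5 each) differed by less than the spread between palms (exact two-sided permutation p = 0.444). On the second component the means were -1.1 ± 48.6 and 1.1 ± 73.9 (exact permutation p = 0.976).

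**Figure D3:**
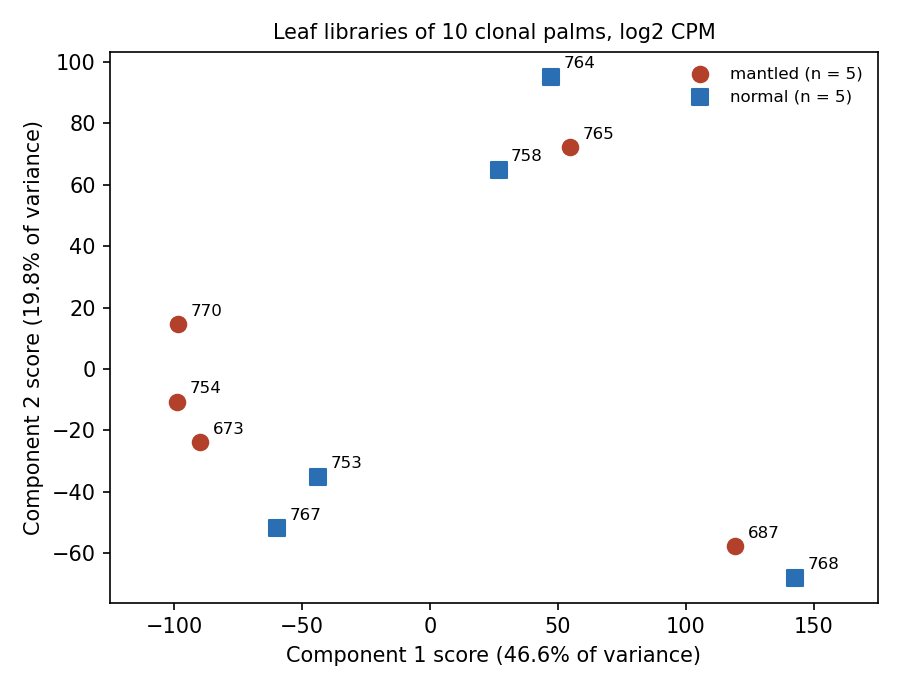
Scores of the 10 palms on the first (horizontal) and second (vertical) principal components of log2 CPM, in arbitrary units, labelled by palm number, with mantled palms as red circles and normal palms as blue squares. Mantled palm 687 lies beside normal palm 768, and mantled palm 765 beside normal palms 758 and 764.

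Phenotype accounted for 6.88% of the total variance in log2 CPM. Across all 252 assignments of the palms to 5 and 5 the mean was 11.1% and the highest value 41.7% (exact permutation p = 0.738 for a share as large). Pearson's r over units, which are not independent replicates, averaged 0.888 over the 20 pairs of palms with the same phenotype and 0.897 over the 25 pairs with different phenotypes (exact permutation p = 0.722, one-sided for a higher value within groups). The closest palm had the same phenotype for 5 of the 10 palms. The most alike pair was mantled replicates 1 and 3 (r = 0.965), and normal replicate 4 resembled mantled replicate 3 nearly as closely (r = 0.961). The least alike pair was mantled replicate 5 and normal replicate 5 (r = 0.780), while within the mantled group replicates 2 and 5 had r = 0.805.

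No difference in library measures between phenotypes was detected. Of 9 measures, including assigned reads, unassigned classes and the TMM factor, the lowest adjusted p was 0.843 (exact two-sided permutation tests, Benjamini-Hochberg adjusted). Mantled palms had 11660400 ± 756289 assigned reads and normal palms 11234600 ± 874153 (SD, n = 5 each; exact permutation p = 0.405). Units with at least 10 reads numbered 33201 ± 2717 in mantled and 31746 ± 1097 in normal palms (exact permutation p = 0.286). The 10 most abundant units held 3.80 ± 0.29% of assigned reads in mantled and 5.33 ± 3.43% in normal palms (exact permutation p = 0.468), and the gap rested on normal replicate 5, without which the difference was -0.0274 percentage points. MAKER-style units held 47.6 ± 0.71% and 47.8 ± 2.17% of reads (exact permutation p = 0.881).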

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

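The tests on 2 surrogate variables, on splits by count of calls and without the 100 most abundant units were chosen only after the result was seen.

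Within each group of 5 palms, 30 sets of values (library measures, component scores and the named units) were searched for a palm far from the others. In all, 3 were found, where chance flags about 1 in 20 sets, so they are no clear excess over chance. The sets are not independent, and the named units were chosen by p-value from the same counts. In mantled replicate 1, 31.87% of listed reads fell in no unit, where the other mantled palms had 34.5% to 35.4%. In normal replicate 5, the 10 most abundant units held 11.33% of the assigned reads, where the other normal palms had 3.02% to 5.01%. The log2 CPM of p5_sc00054_cds_16.5 was 6.277 in normal replicate 5, where the other normal palms had 1.88 to 3.11.

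In normal replicate 5, the 10 most abundant units lay on 7 scaffolds, and the same units held 1.10% to 4.14% of reads in the other 9 palms. This palm also had 27 units, of 25 stems, at least 8-fold above every other palm, holding 4.62% of its reads. Mantled replicate 2 had 2 such units and normal replicate 1 had 1, while the remaining 7 palms had 0. The labels give nothing that sets normal replicate 5 apart, and no biological explanation was tested.

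The absence of calls between phenotypes (0 units) was set against 3 explanations. Every split gives at least 0 calls, so the count for the 100 splits drawn of 126 (100 as large) says nothing about chance. Among those drawn, the highest other count was 13 units, and 2 splits gave any call. The split with the most units whose values did not overlap (5468) was not drawn. Variation between palms unrelated to phenotype could hide many differences. With 2 surrogate variables as covariates 0 units passed, where 62% of 50 simulated 4-fold changes were called, which argues against many hidden differences of that size. However, the count at unadjusted p under 0.05 rose from 389 to 956 with 2 surrogate variables and to 1749 with 3. It was 7525 with limma-voom quality weights and 2300 without mantled replicate 2. Estimates of the number of surrogate variables were 2 and 6. These settings were not run on other splits, so many differences of smaller size stay open. With the labels of 1 mantled and 1 normal palm exchanged, each of 21 splits gave 0 called units (4 of the 25 possible were not run), but small differences would give 0 either way, so an exchange stays open; their counts at unadjusted p under 0.05 (147 to 6226, above the real 389 in 14) do not bear on it, since of the 99 other splits drawn 19 had fewer than 389 and the median was 1100. Differences of 2-fold remain open in many units, though the unadjusted 95% interval excluded a change of that size for 13422 units (41.6%). Of 50 simulated 2-fold changes, 10% were called with 2 surrogate variables and 0% without, and no larger number was simulated at that fold. Differences of 4-fold in few units remain open in part, with 62% and 28% called.

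The spread of the palms along the first component, which did not separate the phenotypes, was set against 2 technical explanations. A difference in depth between libraries was removed by thinning every library to 10236532 reads, and the new first component had an absolute r of 1 with the old one across palms, to 4 digits. This argues against depth as the cause. Palms 754 and 768, at the ends of the component with scores of -98.8 and 142.9, also had similar totals of 12043560 and 12522062 reads. For a few abundant units, the absolute r was again 1 without the 100 with the most reads, and the first component held 46.7% of the variance. The component therefore does not rest on those 100 units. This outcome was nearly fixed in advance, since so few of 32285 units could hardly move a component of log values, so nothing further is drawn from it. Growing conditions, sampling date, tissue mixture, RNA quality and sequencing batch stay open and untested, since the labels give no values for them and the units have no gene names to serve as markers.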

How the results depend on the processing

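The tests with 2 or 3 surrogate variables, without palms 687 and 768 together, per stem and on MAKER-style units were chosen only after the data were seen. The count of 0 units past adjusted p 0.05 held in 24 of 25 alternatives, among them every palm left out in turn (0 to 0 units), and so did the count of 0 with at least 2-fold change. With 3 surrogate variables 1 unit passed both (maker-p5_sc02390-augustus-gene-0.14-mRNA-1:cds, log2 difference 2.41, edgeR adjusted p = 0.0113, where the lowest adjusted p over the alternatives ran from that value to 1); its log2 difference without covariates was 2.54 with a standard error of 1.68. The cause was not tested. The next lowest adjusted p was 0.135 with limma-voom quality weights, which gave mantled replicate 2 a weight of 0.25 and normal replicate 5 a weight of 0.37, and 0.679 without mantled replicate 2. The count at unadjusted p under 0.05 was less stable. From 389 of 32285 it became 136 to 2300 with 1 palm left out (the extremes without mantled replicates 5 and 2). It was 1685 with palms 753 to 770 alone, 7525 with limma-voom weights, and 956 and 1749 with 2 and 3 surrogate variables. Without the filter on low counts, edgeR gave 1968 of 80122 units and DESeq2 937 of 79866. Leaving out mantled replicates 3 or 4, or normal replicates 3 or 4, gave 234, 1111, 610 and 774. Without palms 687 and 768 together it was 1518, with 0 calls. Summed per stem, 18030 stems were tested and 0 passed (135 at unadjusted p under 0.05), and of MAKER-style units alone 0 of 6172 passed. The 4 named units kept their direction and stayed above the threshold in each alternative that tested them, and the log2 difference of p5_sc00054_cds_16.5 ranged from -2.80 to -0.84, the latter without normal replicate 5. The phenotype's share of variance was 5.92% to 6.89% in 4 alternatives, and no library measure reached p under 0.05 with any palm left out. The sum per gene through a reference and the alternatives for gene lists were not run, since the tables and the reference used here gave no gene names for the units. No paired analysis was possible because the labels give the palms no shared replicate numbers. At 10236532 to 12544294 reads per palm, 0 of 50 simulated 2-fold changes were called, which limits what can be seen. The share called also depended on the number of changed units: 28% of 50 and 76.5% of 2000 units changed 4-fold. Units with a mean count under 20 were not simulated.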

Other observations

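The test of pairs of units within stems and the test of the stems of scaffold 107 were chosen only after the result was seen.

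Most other splits of the palms separated at least as many units as the phenotype, and 16 of 126 separated fewer. The split with the highest count, that of palms 673, 753, 754, 767 and 770 from palms 687, 758, 764, 765 and 768, which mixes phenotypes in both parts and was picked from these values, gave 5468 units whose values did not overlap, against 40 for the phenotype and 256 expected by chance with independent palms. Of all 126 splits, 110 gave at least as many such units as the phenotype, so chance cannot be excluded for the 40, and the median of the other splits was 130. The split follows the sign of the first-component scores and restates that structure of the samples, so it is no independent evidence of it. It was found from the expression values and is not a group of the study.

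The counting units may be segments of genes rather than whole genes. Among tested units with numbered cds IDs, 14755 neighbouring pairs within a stem had a median r of 0.696 across the 10 palms, against 0.081 for 10114 neighbouring pairs of different stems on the same scaffold and -0.01 for random pairs. The difference of 0.615 is in line with the hypothesis that units of 1 stem are segments of 1 gene. The tables hold 18394 such stems with a median of 4 units, and 53 at most. If so, a read that spans several segments would be ambiguous, a candidate source of part of the 18.2% to 20.6% of reads in that class, which was not tested further. Tests over units then count some genes several times, and summing per stem gave 0 calls as well.

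A gain or loss of a scaffold-sized segment in 1 palm, as may arise in tissue culture, was tested on 207 scaffolds with at least 30 tested units. The lowest median deviation from the palms' median was -1.20, in normal replicate 5 on scaffold 107 (30 units), and the highest 0.77, in the same palm on scaffold 228 (39 units). Both passed the bounds of -0.8 and 0.5 set in advance for a loss or a gain, and 21 of 2070 medians lay beyond -0.5 or 0.4. A change of a whole scaffold would shift all its stems, on top of each stem's own variation between palms. The 16 stems of scaffold 107 ranged from -4.45 to 0.64, with 13 below 0 and an upper quartile of -0.15. The 21 stems of scaffold 228 ranged from -2.90 to 2.53, with 13 above 0 and a lower quartile of -0.46. These quartiles missed the values predicted for a whole-scaffold change, -0.8 or lower and 0.4 or higher. The spread of stems in this palm without such a change was not measured, so the quartiles cannot decide the question. A loss or gain of these scaffolds, of smaller segments or of the other scaffolds stays open.

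In normal replicate 5, p5_sc00049_cds_4.1 had 94 reads and p5_sc00049_cds_4.2 had 62, where no other palm had more than 1 read of either. These were the only units, in any palm, with at least 20 reads in 1 palm and at most 1 in each of the other 9, and they were chosen after their values were seen.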
